A study of Mus musculus with 12 samples.

How the data were processed

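The series holds 12 libraries of 3′-end poly(A) RNA sequencing from mouse cells of the C57BL/6 strain. They come from embryonic stem cells (ESCs) and embryoid bodies (EBs), each wild type (WT) or Mettl3 knockout (KO), at 0, 4 and 8 h after actinomycin. Groups were taken from the sample titles, with 1 library in each of the 12 groups. Nothing in the labels says whether the 3 times of a condition (a genotype in a cell type) share a culture, so p-values measure the scatter between these libraries and not the variation between cultures or knockout lines.

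The authors deposited 1 table of normalized levels per RefSeq transcript, a signal that is never below 0, for all 12 libraries. The submitters' processing notes name CASAVA 1.8.2, Bowtie, Bowtie2 2.1.0 and the mm10 build. How levels were counted and scaled is not given in the sources used here. The deposited signal was read as it stands, in the file's own units. Per the labels' protocols, RNA was fragmented, poly(A) ends were selected and first-strand synthesis kept the strand. The table has 12 columns, and each column name matched 1 sample title.

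The table has 19746 entries, of which 19535 were matched to symbols by RefSeq ID in a table of mouse genes on assembly GRCm38.p6, 98 more in the GENCODE annotation, and 113 stayed under their ID. Dropping 38 identical duplicates left 19708 entries, among which 118 share a symbol with another. Coordinates are those of GRCm38 (mm10), counted from 1. At least 99.8% of the values under 100 in each library were whole multiples of a step particular to that library, within 0.1 of a step. The commonest low values were multiples of 50 steps. Taking 50 steps as 1 read, an inference from the values that nothing in the labels states, the libraries hold 208874 to 666804 read equivalents. The 95% intervals printed beside single levels are exact Poisson intervals on those read equivalents. They cover counting error only, since no molecular identifiers were used to tell molecules from PCR copies. Because the steps are fractions of a read, whole counts were not recovered and no count model was run. Column totals of the deposited signal differed by 3.02-fold between libraries, so the levels had not been set to equal totals.

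Differences were tested with limma 3.58.1 in R 4.3.3 on log2(level + 8.58), where 8.58 is 1 ppm of the mean column total. On that scale the change of a low gene is understated. Genes with a mean level of at least 42.9 (5 ppm) over the 12 libraries were tested, 12704 in all. The fit has 8 coefficients: an intercept and a straight line over hours for each of the 4 conditions. It leaves 4 residual degrees of freedom, with a trended variance prior worth 11.1 more. The spread is the scatter of each condition's 3 libraries around its own line, pooled over the conditions. It therefore holds library noise and curvature over time. Level differences are means over 0, 4 and 8 h, so for short-lived transcripts they mix the untreated level with decay. Slope differences compare the change per hour. Slopes are relative to the deposited scaling and are not half-lives. Adjusted p-values are Benjamini-Hochberg over the genes tested, with a threshold of 0.05, and errors are limma's standard errors (SE). Values at 0 h are single libraries and carry no test.

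Genes are named by a rule written before the data were examined. Mettl3 comes first, and 9 pluripotency genes are named in every comparison. For each level difference the rule takes the 8 called genes with the largest rise and the 8 with the largest fall, provided that the sign is the same at 0, 4 and 8 h. For the mean slope it takes the 8 steepest called falls seen in all 4 conditions, and the 8 largest rises likewise. For the difference between cell types and for slope differences it takes the 6 largest in each direction, or the 3 with the smallest p where none is called. Up to 4 members of each gene list follow. Entries without a symbol and Rik or Gm symbols are named only among the first 4 of a direction.

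The 25 gene lists fixed before the data were examined are m6A machinery, naive pluripotency, core pluripotency, formative and primed pluripotency, neural, mesoderm and heart, definitive and visceral endoderm, parietal endoderm and basement membrane, primitive blood and endothelium, fibroblast and feeder, trophoblast, germ line and 2-cell-like, immediate early and short-lived, p53 targets, glycolysis, cell cycle, RNA decay machinery, cholesterol synthesis, ribosomal proteins, mitochondrial ribosomal proteins, oxidative phosphorylation, proteasome, zinc-finger genes with Zfp-type symbols, histone clusters and Hox genes. Members were matched by current symbol, then by older symbol. Elavl3, Tcstv1 and Jund were not found in the table, and 0 of the 28 Hox genes passed the filter on low levels. A list of 1421 genes of families that should be silent in these cells (olfactory, vomeronasal and trace amine receptors, keratin-associated proteins and defensins) was added after the data were seen, to measure background. For each list the calls were counted over all genes tested and with p adjusted over the list alone. The median of each list was placed among 10000 random lists of the same size drawn from 20 bins of mean expression, which describes these libraries and is no p-value.

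The fit was tested on simulated data with the genes of these data and their fitted lines, KO and WT averaged. The simulated scatter was Poisson counting error plus a fixed log2 noise, the same for every gene, in place of the real residual spread. The rates below hold for that scatter only. Of 100 genes changed by a log2 of 1 between KO and WT ESCs, 24% were called, and of 100 changed by a log2 of 2, 55%. No changed gene was called with the wrong sign, and 14 of the unchanged genes were called falsely. For slope differences in ESCs, 26% of changes of 0.25 per hour and 49% of changes of 0.50 per hour were called, with 11 false calls. Alternatives chosen before the data were examined were pseudocounts of 0.2 and 5 ppm, no filter or a filter of 20 ppm, and 3 rescalings of the libraries (equal column totals, median ratio to the geometric mean, or equal medians of the ribosomal protein genes). Others were a curvature term shared by the conditions, no variance trend, additive time terms and each library left out in turn. A step in place of the line, a fit without both EB libraries of 8 h, a subtraction of 3 times the mean level of the silent families and list medians relative to all genes were added after the data were seen, as were list medians at each time alone. The lines are centred at 4 h. Without its 0 or 8 h library, the level of a condition is therefore that of its 4 h library alone. Without its 4 h library it is the mean of 0 and 8 h. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for lists, intervals and plots.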

Results

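Transcript 3′ ends were sequenced from mouse embryonic stem cells (ESCs) kept in serum-free medium with LIF and the inhibitor pair called 2i, and from embryoid bodies (EBs), which are aggregates of differentiating cells grown from ESCs in serum medium. Both were wild type (WT) or knockout (KO) for Mettl3, the gene of the catalytic subunit of the complex that writes the m6A mark on adenosines of mRNA. Cells were collected 0, 4 and 8 h after actinomycin, which blocks transcription, so that a fall after 0 h follows the loss of existing transcripts. The series concerns the part m6A plays when cells leave the naive pluripotent state. Each genotype, cell type and time had 1 library, 12 in all, and no group had a replicate.

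Column totals of the deposited levels were 11023612, 11085581 and 10057266 in WT ESCs at 0, 4 and 8 h, and 10449707, 10983821 and 11086748 in KO ESCs. In WT EBs they were 8311484, 6056954 and 3673848, and in KO EBs 7076737, 6877207 and 6249922. Read equivalents inferred from the steps of the values ran from 208874 in WT EBs at 8 h to 666804 in KO EBs at 0 h. Genes of families that should be silent in these cells had a level above 0 for 26.7 to 34.1% of 1421 members in WT EBs and 34.0 to 36.2% in KO EBs. In WT ESCs the share was 6.69 to 9.50%, and in KO ESCs 6.97 to 9.15%.

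Mettl3 itself (NM_019721, chromosome 14, 52294841 to 52308741 on GRCm38) had levels of 251, 64.8 and 113 in WT ESCs at 0, 4 and 8 h, against 98.1, 65.4 and 41.8 in KO ESCs. In WT EBs the levels were 175, 86.0 and 77.4, and in KO EBs 16.8, 40.7 and 84.0. At 0 h the KO level was lower in both cell types, with 95% counting intervals of 26.1 to 254 against 125 to 450 in ESCs, which overlap, and of 1.34 to 69.5 against 90.4 to 307 in EBs, which do not. The KO level was not below the WT level in ESCs at 4 h or in EBs at 8 h. Over the 3 times the difference was -0.84 ± 0.52 in ESCs (log2, SE; limma adjusted p 0.311) and -1.23 ± 0.52 in EBs (adjusted p 0.175). The labels do not say which part of the gene was deleted, and a 3′ tag outside that part checks nothing.

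The first comparison asks what loss of Mettl3 changes in ESCs held in the naive state. Klf2, a transcription factor of naive pluripotency, was higher in KO than in WT ESCs by a log2 of 3.97 ± 0.45 (adjusted p 5.79e-05). Klf4, a related factor, was higher by 1.53 ± 0.32 (adjusted p 0.00519) and Sox2, a core pluripotency factor, by 1.66 ± 0.44 (adjusted p 0.0211), as means over 0, 4 and 8 h. Pou5f1, which encodes Oct4, was lower, with a log2 difference of -0.97 ± 0.15 (adjusted p 0.000745). Differences for Nanog (0.28 ± 0.23), Esrrb (0.43 ± 0.25), Zfp42 (0.80 ± 0.29), Tfcp2l1 (-0.82 ± 0.27) and Tbx3 (0.00 ± 0.39) did not pass. At 0 h alone, in single untreated libraries with no test, the level in KO against WT ESCs (log2 difference in parentheses) was 13480 against 5550 for Klf2 (1.28), 4458 against 2671 for Sox2 (0.74), 4187 against 4057 for Nanog (0.04) and 2008 against 2547 for Klf4 (-0.34). It was 15830 against 32680 for Pou5f1 (-1.04), 4011 against 8661 for Zfp42 (-1.11), 1980 against 3186 for Esrrb (-0.68), 2597 against 3491 for Tfcp2l1 (-0.42) and 510.5 against 1434 for Tbx3 (-1.48). Klf4 was thus not higher before actinomycin, and its difference over the 3 times lay in the treated libraries. Without the KO ESC library of 0 h, or without that of 8 h, the calls of Klf4 (1.48) and Pou5f1 (-0.82) were lost. The KO level in either fit is that of 4 h alone, not a mean over the 3 times. The call of Sox2 was lost without the KO ESC library of 0 h (1.47), 4 h (1.75) or 8 h (1.47) and without the WT ESC library of 4 h (0.98). Klf4 lost its call with additive time terms, Pou5f1 and Sox2 without the variance trend, and Sox2 with no filter on low levels.

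In KO ESCs, the trophoblast list had 5 higher, 0 lower and 3 not past the threshold of 8 tested (5 and 0 adjusted over the list alone), with a median of 2.17 at 0 h alone. The higher ones included the keratins Krt8 (3.46 ± 0.29) and Krt18 (3.84 ± 0.66) and the transcription factor Tfap2c (3.73 ± 0.37). Krt7 was listed at 0 in all 3 WT ESC libraries and at 125, 118 and 283 in KO ESCs. The 8 largest rises with 1 sign at all times also held the entry NR_001592 (5.26 ± 0.23), for which no symbol was matched, and Trp53rkb (5.17 ± 0.43), which has a close copy in Trp53rka. The neuronal intermediate filament gene Ina (4.68 ± 0.56), the Wnt receptor gene Fzd2 (4.50 ± 0.63), the Wnt ligand gene Wnt7b (4.46 ± 0.59), Tmem121 (4.44 ± 0.40) and Krtdap (4.42 ± 0.69) made up the rest with Krt7. The largest falls were Islr2 (-5.46 ± 0.56), Tex13b (-5.01 ± 0.61), Usp26 (-4.61 ± 0.57), Pnma5 (-4.35 ± 0.68), Icosl (-3.40 ± 0.63) and Taf7l (-3.37 ± 0.69). Tmem179 and Tlx2 were among them too, listed at 0 in all 3 KO ESC libraries and at 180.0, 88.6 and 78.5 (Tmem179) and 45, 99.5 and 188 (Tlx2) in WT ESCs. Taf7l and Mael (-2.47 ± 0.73) were the called members of the germ line and 2-cell-like list, with 0 higher and 2 lower of 8 (0 and 3 adjusted over the list alone).

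The m6A machinery list had 7 higher, 0 lower and 8 not past the threshold of 15 tested (9 and 0 adjusted over the list alone), with Mettl3 not passing. Its median difference was 0.72 at 0 h alone (9 higher and 6 lower), 1.25 at 4 h and 1.57 at 8 h, so that part of it lay in the treated libraries. Higher genes included the reader genes Ythdf2 (2.45 ± 0.24) and Ythdf1 (2.09 ± 0.36) and the writer subunit genes Rbm15 (2.39 ± 0.32) and Rbm15b (2.41 ± 0.31). The p53 target list had 7 higher and 0 lower of 19 (8 and 1 adjusted over the list alone), with Phlda3 at 2.00 ± 0.25 and Bbc3, which encodes the pro-apoptotic protein Puma, at 1.98 ± 0.33. The immediate early list had a median of -0.57 at 0 h alone and 1.43 at 8 h. In it 4 higher and 0 lower of 27 (4 and 0 adjusted over the list alone) were called, with Mycn at 3.73 ± 0.37 and Jun at 2.92 ± 0.59. Mitochondrial ribosomal protein genes had 22 higher and 1 lower of 75 (24 and 1 adjusted over the list alone), led by Mrpl43 (3.05 ± 0.27) and Mrps2 (3.07 ± 0.30). Zinc-finger genes had 49 higher and 0 lower of 307 (49 and 1 adjusted over the list alone). The list medians at 0, 4 and 8 h alone were 0.26, 0.73 and 1.05 for p53 targets, 0.14, 0.43 and 0.82 for mitochondrial ribosomal proteins, and 0.13, 0.60 and 0.65 for zinc-finger genes, so that most of these differences lay in the treated libraries. The median of all genes was 0.03, 0.23 and 0.26. Glycolysis genes had 0 higher and 7 lower of 18 (0 and 9 adjusted over the list alone), with a median of -0.86 at 0 h alone. Lower ones included Pgk1 (-1.38 ± 0.17), Aldoa (-1.12 ± 0.15) and Ldha (-1.12 ± 0.18). Oxidative phosphorylation genes had 1 higher and 9 lower of 77 (1 and 9 adjusted over the list alone). The medians of 4 more lists changed sign with the scaling. Cholesterol synthesis genes had 0 higher and 0 lower of 19 (0 and 0 adjusted over the list alone) and RNA decay machinery genes 0 higher and 1 lower of 24 (0 and 0 adjusted over the list alone). Ribosomal protein genes had 4 higher and 4 lower of 86 (4 and 2 adjusted over the list alone) and histone genes 0 higher and 0 lower of 21 (0 and 0 adjusted over the list alone). Cell cycle genes had 1 higher and 4 lower of 29 (1 and 6 adjusted over the list alone), which turned to 4 higher and 2 lower under ribosomal protein scaling. Proteasome genes had 1 higher and 3 lower of 37 (1 and 1 adjusted over the list alone), which turned to 2 higher and 1 lower.

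The naive list split, with 3 higher and 1 lower of 20 (3 and 2 adjusted over the list alone): Klf2, Klf4 and Dppa3 (2.32 ± 0.48) were higher, and Tet2, which encodes an enzyme that oxidizes 5-methylcytosine, was lower (-1.54 ± 0.29). The core list had 3 higher and 4 lower of 18 (3 and 5 adjusted over the list alone), with Dppa5a (-1.66 ± 0.19) and Tdgf1 (-1.50 ± 0.18) lower and Gdf3 higher (0.95 ± 0.21). Formative and primed genes had 3 higher and 0 lower of 14 (5 and 0 adjusted over the list alone), with the DNA methyltransferase gene Dnmt3b at 1.29 ± 0.24 and Cldn6 at 2.09 ± 0.42. In the fibroblast and feeder list S100a6 was higher (2.04 ± 0.19) and Fn1 lower (-1.03 ± 0.21), 1 higher and 1 lower of 12 (1 and 1 adjusted over the list alone). The medians of the core and fibroblast lists changed sign with the scaling. By limma, 1381 genes were higher and 416 lower in KO ESCs, 1797 of 12704 tested, and 1270 and 403 of them kept 1 sign at 0, 4 and 8 h. The median over all genes was 0.18 as deposited, 0.02 under median-ratio scaling and 0.34 under ribosomal protein scaling. Relative to it the list medians were 3.03 for trophoblast, 0.79 for m6A machinery and -0.64 for glycolysis. Median-ratio scaling gave 1050 higher and 673 lower. The total fell to 1047 without the variance trend, 1043 with additive time terms, 737 without the KO ESC library of 0 h and 717 without that of 8 h. In the fits without a library the KO level is that of 4 h alone.

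**Figure D1:**
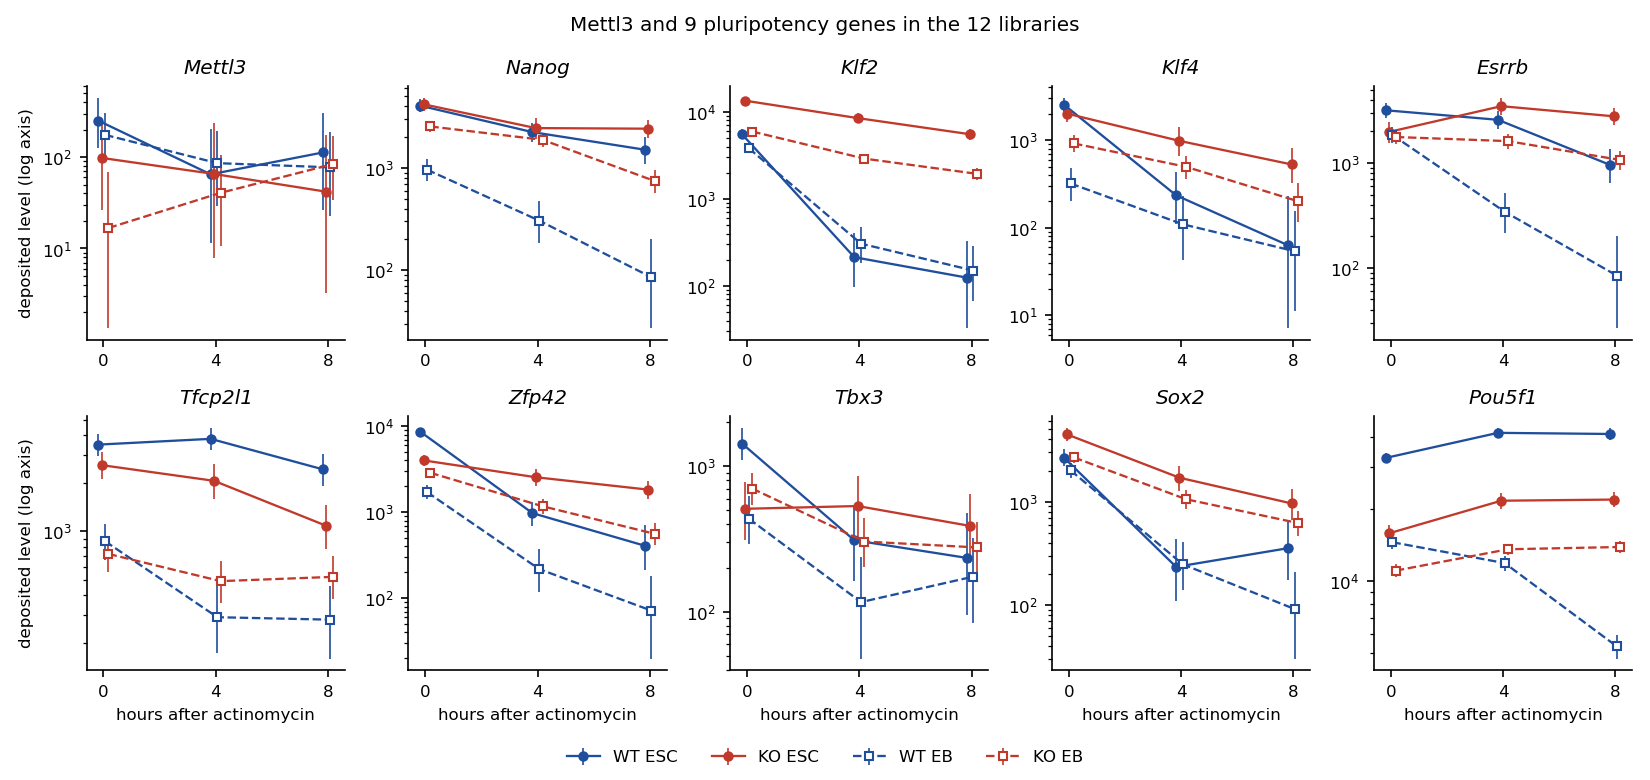
Deposited levels of Mettl3 and 9 pluripotency genes (log axis, the file's own units) against hours after actinomycin in the 12 libraries; each point is 1 library, bars are 95% counting intervals from inferred read equivalents, blue is WT, red is KO, filled circles are ESCs and open squares EBs. Klf2 fell from 5550 to 125 in WT ESCs and from 13480 to 5555 in KO ESCs between 0 and 8 h.

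The same comparison in EBs asks what loss of Mettl3 changes once cells are made to differentiate. Most tested members of the lists of endoderm and of the basement membrane it lays down were lower in KO than in WT EBs. The definitive and visceral endoderm list had 0 higher, 11 lower and 4 not past the threshold of 15 tested (0 and 13 adjusted over the list alone). Lower genes included the secreted proteins Afp, alpha-fetoprotein (-4.83 ± 0.38), and Ttr, transthyretin (-6.15 ± 0.56), and the endocytic adaptor gene Dab2 (-3.94 ± 0.57). The parietal endoderm and basement membrane list had 0 higher, 9 lower and 3 not past the threshold of 12 tested (0 and 10 adjusted over the list alone). Lower genes here included the collagen gene Col4a1 (-5.04 ± 0.36), the laminin genes Lama1 (-4.49 ± 0.36) and Lamb1 (-3.79 ± 0.26), and Sparc (-2.68 ± 0.18). At 0 h alone, the median differences of these lists were -3.26 and -3.35, with 15 of 15 and 12 of 12 genes lower. Afp stood at 2450 in WT EBs at 0 h and 55.4 in KO EBs, against 37.2 and 54.8 in WT and KO ESCs.

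Of the 9 pluripotency genes, 6 were higher in KO EBs. Nanog was higher by 2.33 ± 0.23 (adjusted p 1.48e-05), Zfp42 by 1.98 ± 0.29 (adjusted p 0.000497), Esrrb by 1.89 ± 0.25 (adjusted p 0.000206), Klf2 by 2.49 ± 0.45 (adjusted p 0.00234), Klf4 by 1.78 ± 0.32 (adjusted p 0.0022) and Sox2 by 1.71 ± 0.44 (adjusted p 0.0233). Differences for Tbx3 (0.88 ± 0.39), Tfcp2l1 (0.45 ± 0.27) and Pou5f1 (0.39 ± 0.15) did not pass. In the single libraries of 0 h, again with log2 differences in parentheses, the level in KO against WT EBs was 2542 against 963 for Nanog (1.39), 2877 against 1717 for Zfp42 (0.74), 5969 against 3836 for Klf2 (0.64), 917 against 320.1 for Klf4 (1.49), 2675 against 2007 for Sox2 (0.41) and 704 against 437 for Tbx3 (0.68). It was 1771 against 1852 for Esrrb (-0.06), 722 against 867 for Tfcp2l1 (-0.26) and 11060 against 14530 for Pou5f1 (-0.39), so that Esrrb was not higher before actinomycin. The naive list had 5 higher and 0 lower of 20 (6 and 1 adjusted over the list alone). The core list had 7 higher and 1 lower of 18 (9 and 1 adjusted over the list alone), with Jarid2 at 1.95 ± 0.28 and Utf1 at 1.37 ± 0.25 higher and Lin28a lower (-1.38 ± 0.30). At 0 h alone the list medians were -0.09 for naive and -0.18 for core genes, and at 8 h 1.098 and 1.43, so that these list differences lay in the treated libraries. The median of all genes was -0.18 at 0 h and 0.38 at 8 h. Without the KO EB library of 0 h, or that of 8 h, the calls of Klf2 (2.34) and Klf4 (1.91) were lost. The KO level is then that of 4 h alone. Klf2 lost its call without the variance trend, and Klf4 with additive time terms. Both lost it without the pair of EB libraries of 8 h (3.21 and 2.095), where the difference is that of 4 h alone. Sox2 lost its call without the variance trend, with no filter on low levels and without any 1 of the 6 EB libraries (1.44 to 2.24), under equal column totals (1.49) and under ribosomal protein scaling (1.40).

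The largest falls in KO EBs, besides Ttr, Col4a1 and Afp, were Spink1 (-7.01 ± 0.36), the calcium-binding protein gene S100g (-6.04 ± 0.50), Pga5 (-4.91 ± 0.40), Lgals2 (-4.73 ± 0.96) and Gkn1 (-4.69 ± 0.82). The largest rises were Trp53rkb (4.63 ± 0.43), Dnajb13 (4.14 ± 0.55), Rpl10l, a copy of Rpl10 (3.62 ± 0.30), Col9a2 (3.59 ± 0.34), Mesp2 (3.54 ± 0.80), Cilp2 (3.49 ± 0.82), the embryonic Ras gene Eras (3.46 ± 0.35) and Ccdc113 (3.44 ± 0.58). The m6A machinery list had 6 higher and 0 lower of 15 (7 and 0 adjusted over the list alone), with medians of 0.03 at 0 h alone and 1.33 at 8 h, so that its difference lay in the treated libraries. Its called genes included Ythdf2 at 2.35 ± 0.24 and Wtap, a subunit of the writer complex, at 1.67 ± 0.26. The p53 target list had 7 higher and 0 lower of 19 (9 and 0 adjusted over the list alone), with Aen at 2.42 ± 0.32 and Bax at 0.96 ± 0.16. Mitochondrial ribosomal protein genes had 29 higher and 0 lower of 75 (40 and 0 adjusted over the list alone). Cytoplasmic ones had 20 higher and 0 lower of 86 (36 and 0 adjusted over the list alone). At 0 h alone the medians were 0.16 and -0.22, and that of p53 targets 0.37. The fibroblast and feeder list had 0 higher and 3 lower of 12 (0 and 7 adjusted over the list alone), among them Vim (-1.54 ± 0.26), Thy1 (-1.76 ± 0.42) and Fn1 (-0.84 ± 0.21). Neural genes had 1 higher and 0 lower of 11 (1 and 0 adjusted over the list alone). Mesoderm and heart genes had 1 higher and 0 lower of 10 (1 and 0 adjusted over the list alone), and blood and endothelium genes 0 higher and 0 lower of 6 (0 and 0 adjusted over the list alone). By limma, 973 genes were higher and 198 lower in KO EBs, of which 845 and 191 kept 1 sign at 0, 4 and 8 h.

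The median over all genes was 0.09 as deposited and turned to -0.14 under equal column totals, -0.09 under median-ratio scaling and -0.22 under ribosomal protein scaling. Relative to it, list medians were -2.49 for definitive and visceral endoderm, -3.32 for parietal endoderm, 0.53 for naive pluripotency and 0.79 for m6A machinery. The calls split into 632 higher and 359 lower under equal column totals, 656 and 272 under median-ratio scaling, and 505 and 430 under ribosomal protein scaling. Both endoderm lists held 9 to 13 lower and 0 higher calls each under every scaling. The total of 1171 became 353 without the variance trend, 475 with additive time terms, 126 without both EB libraries of 8 h and 1803 with background subtracted. It was 257, 620 and 251 without the KO EB library of 0, 4 or 8 h, and 490 and 482 without the WT EB library of 0 or 8 h. A level without its library of 0 or 8 h is that of 4 h alone.

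The change from ESC to EB was then compared within each genotype. In WT cells, the definitive and visceral endoderm list had 10 higher and 1 lower of 15 (10 and 2 adjusted over the list alone). Parietal endoderm had 10 higher and 0 lower of 12 (10 and 0 adjusted over the list alone). The largest rises were S100g (6.76 ± 0.50), the plasminogen activator gene Plat (6.23 ± 0.70), Gkn2 (5.71 ± 0.66), the apolipoprotein gene Apoa1 (5.36 ± 0.68) and Ttr (5.64 ± 0.56). The water channel gene Aqp8, Apom and Cck were listed at 0 in all 3 WT ESC libraries and at 463, 501 and 396 in WT EBs at 0 h. The fibroblast and feeder list had 7 higher and 1 lower of 12 (7 and 1 adjusted over the list alone), with Thy1 at 2.36 ± 0.42 and Mgp at 3.46 ± 0.77. The trophoblast list had 4 higher and 0 lower of 8 (4 and 0 adjusted over the list alone), with Krt8 at 4.29 ± 0.29. The immediate early list had 6 higher and 2 lower of 27 (5 and 2 adjusted over the list alone), with Jun at 2.82 ± 0.59. Its median was -0.02 at 0 h alone (13 higher and 14 lower), against 0.54 over the 3 times. The naive list had 1 higher and 13 lower of 20 (1 and 14 adjusted over the list alone). The core list had 0 higher and 14 lower of 18 (0 and 15 adjusted over the list alone). Among them were Nanog (-2.97 ± 0.23), Tfcp2l1 (-2.92 ± 0.27), Esrrb (-2.35 ± 0.25), Zfp42 (-2.27 ± 0.29), Pou5f1 (-1.97 ± 0.15), Klf4 (-1.40 ± 0.32) and Tbx3 (-1.15 ± 0.39), while Sox2 (-0.73 ± 0.44) and Klf2 (0.07 ± 0.45) did not pass. The largest falls were Mras (-4.12 ± 0.36), Tex13b (-3.92 ± 0.61), 2810459M11Rik (-3.79 ± 0.26), 2210409E12Rik (-3.79 ± 0.27), Usp26 (-3.60 ± 0.57), Tom1l2 (-3.55 ± 0.26), Pnma5 (-3.48 ± 0.68) and R3hdml (-3.46 ± 0.68).

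By limma, 444 genes were higher and 3701 lower in WT EBs than in WT ESCs, 4145 in all, and 415 and 3403 kept 1 sign at 0, 4 and 8 h. The split turned over with the scaling, to 1405 higher and 607 lower under equal column totals, 1022 and 1002 under median-ratio scaling, and 1433 and 497 under ribosomal protein scaling. The median over all genes was -0.50 as deposited and 0.34, 0.13 and 0.41 under these scalings. Relative to it, list medians were 3.52 for definitive and visceral endoderm, 3.33 for parietal endoderm, 2.28 for fibroblast and feeder, -0.96 for naive and -1.07 for core pluripotency. At 0 h alone, the medians were 3.42, 2.56, 0.67, -1.60 and -0.78 for these lists, against -0.29 for all genes. At 8 h those of the core list and of all genes were -2.17 and -0.74. The total was 1662 without both EB libraries of 8 h, 2119 without the WT EB library of 0 h and 2094 without that of 8 h. In each of these fits the WT EB level is that of 4 h alone.

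In KO cells no rise of the endoderm lists passed the threshold over all genes. By limma, 0 of 15 definitive and visceral endoderm genes were called in either direction (0 adjusted over the list alone), and the list median turned from -0.40 as deposited to 0.15 under equal column totals. Afp had 0.10 ± 0.38 and Ttr -0.65 ± 0.56. The parietal endoderm list had 0 higher and 5 lower of 12 (1 and 7 adjusted over the list alone), with Sparc at -1.56 ± 0.18 and Lama1 at -1.72 ± 0.36. The naive list had 0 higher and 11 lower of 20 (0 and 11 adjusted over the list alone). Among these were Tfcp2l1 (-1.65 ± 0.27), Klf2 (-1.41 ± 0.45), Klf4 (-1.15 ± 0.32), Zfp42 (-1.09 ± 0.29), Nanog (-0.93 ± 0.23) and Esrrb (-0.88 ± 0.25). Only 0, 0 and 1 of these 20 genes were called lower under equal column totals, median-ratio and ribosomal protein scaling. Pou5f1 was lower (-0.61 ± 0.15), and Sox2 (-0.68 ± 0.44) and Tbx3 (-0.27 ± 0.39) did not pass. Rises were led by Hdx (4.13 ± 0.78), the BMP antagonist gene Grem1 (4.08 ± 0.64), Tafa1 (3.58 ± 0.35) and Vmn2r65 (3.49 ± 0.68), the last from a family with close copies that should be silent in these cells. Smcp, Acsm2, Gsdma2 and Prl2c3, of which Gsdma2 and Prl2c3 have close copies as well, were listed at 0 in all 3 KO ESC libraries and at 174, 133, 59.9 and 45.2 in KO EBs at 0 h. Of the genes of silent families, 34.0 to 36.2% were above 0 in KO EBs and 6.97 to 9.15% in KO ESCs. Whether this background gives rises as low as these was not tested for these genes. Falls were led by Msln (-3.51 ± 0.56), Tmprss5 (-3.30 ± 0.83), Trh (-3.30 ± 0.25), Cltb (-3.21 ± 0.38), Mapk11 (-3.15 ± 0.68), Klhl13 (-3.11 ± 0.25), Accsl (-3.05 ± 0.46) and Icam4 (-2.95 ± 0.87).

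At 0 h alone, the log2 difference between EBs and ESCs in WT and in KO cells was -2.07 and -0.72 for Nanog, -0.53 and -1.17 for Klf2, -2.96 and -1.12 for Klf4, -0.78 and -0.16 for Esrrb and -1.998 and -1.83 for Tfcp2l1. It was -2.33 and -0.48 for Zfp42, -1.70 and 0.46 for Tbx3, -0.41 and -0.73 for Sox2 and -1.17 and -0.52 for Pou5f1.

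By limma, 118 genes were higher and 2948 lower in KO EBs than in KO ESCs, with a median over all genes of -0.61. Most of these calls ended with another scaling: 144 higher and 93 lower passed under equal column totals (median 0.05), 96 and 70 under median-ratio scaling (0.03), and 103 and 287 under ribosomal protein scaling (-0.15). The total of 3066 was 111 without the variance trend, 1809 with additive time terms and 278 without both EB libraries of 8 h. It was 183, 1679 and 172 without the KO EB library of 0, 4 or 8 h, and 1020, 1947 and 951 without the KO ESC library of 0, 4 or 8 h. Again a level without its library of 0 or 8 h is that of 4 h alone.

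**Figure D2:**
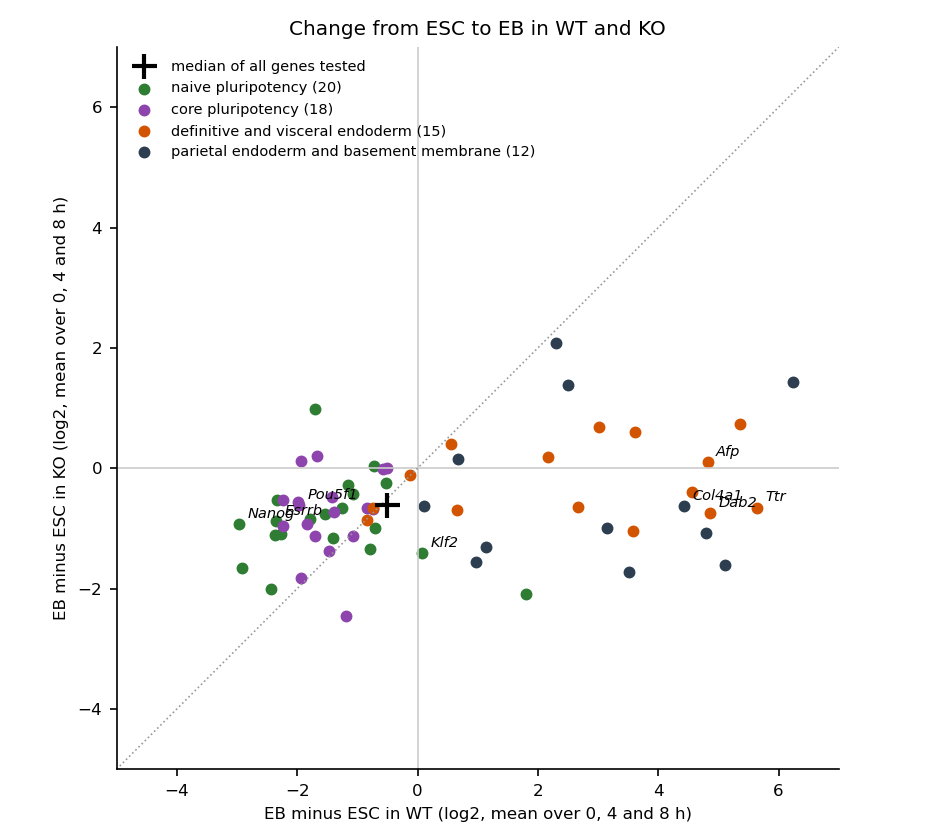
Difference between EBs and ESCs (log2, mean over 0, 4 and 8 h, as deposited) in KO cells against that in WT cells; each point is 1 gene of 4 lists, the cross is the median of all genes tested and the dotted line marks equal change. Afp lies at 4.82 in WT and 0.10 in KO cells, and Nanog at -2.97 and -0.93.

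Whether the change from ESC to EB differed between the genotypes was tested directly. The definitive and visceral endoderm list had 0 higher and 7 lower of 15 (0 and 9 adjusted over the list alone), a lower value standing for a smaller rise in KO cells, among them Afp (-4.71 ± 0.53) and Ttr (-6.29 ± 0.80). Parietal endoderm had 0 higher and 8 lower of 12 (0 and 8 adjusted over the list alone), among them Pth1r (-6.72 ± 0.53) and Lamb1 (-4.14 ± 0.37). In the core list 5 higher and 0 lower of 18 (7 and 1 adjusted over the list alone) were called, and the others did not pass. Higher ones, which fell less in KO cells, included Dppa5a (2.07 ± 0.26) and Pou5f1 (1.36 ± 0.21). The median differences of the core list between EBs and ESCs were -0.78 in WT and -0.47 in KO cells at 0 h alone, and -2.17 and -0.70 at 8 h, so that most of the difference between genotypes lay in the treated libraries. In the naive list Nanog (2.04 ± 0.32), Esrrb (1.47 ± 0.36) and Tet2 (1.82 ± 0.41) were higher and Dppa3 lower (-3.89 ± 0.68), 3 higher and 1 lower of 20 (6 and 1 adjusted over the list alone). Klf2 (-1.48 ± 0.64), Klf4 (0.24 ± 0.45), Tfcp2l1 (1.27 ± 0.38), Zfp42 (1.18 ± 0.42), Tbx3 (0.88 ± 0.56) and Sox2 (0.05 ± 0.63) did not pass. Glycolysis genes had 5 higher and 0 lower of 18 (9 and 0 adjusted over the list alone), with medians between EBs and ESCs of -0.35 in WT and 0.11 in KO cells at 0 h alone and -1.68 and -0.35 at 8 h. The trophoblast list had 0 higher and 4 lower of 8 (0 and 4 adjusted over the list alone). By limma, 191 genes had a higher and 172 a lower difference, 363 in all.

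The split for that difference was 159 higher and 264 lower under equal column totals and 100 and 419 under ribosomal protein scaling, and the median over all genes moved from -0.05 to -0.25 and -0.52. Of the pluripotency and endoderm list medians, none changed sign under the scalings. Relative to all genes they were 0.67 for core, 0.81 for naive, -2.96 for definitive and visceral and -3.29 for parietal endoderm. The total was 204 without a filter on low levels, 613 with shared curvature, 63 without the variance trend and 42 without both EB libraries of 8 h. It was 105, 189 and 96 without the KO EB library of 0, 4 or 8 h, 193 and 177 without the KO ESC library of 0 or 8 h, and 142 and 134 without the WT EB library of 0 or 8 h. Here too a level without its library of 0 or 8 h is that of 4 h alone.

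After actinomycin, the list of immediate early and short-lived transcripts and several lists not chosen by lifetime fell more than the median over all genes. That median was -0.05 log2 per hour and 0.005 under median-ratio scaling. Over the 4 conditions together, immediate early genes had 0 higher and 21 lower of 27 (0 and 23 adjusted over the list alone), among them Mycn at -0.42 ± 0.04 log2 per hour and Dusp1 at -0.42 ± 0.05. Naive genes had 0 higher and 15 lower of 20 (0 and 15 adjusted over the list alone), with Zfp42 at -0.38 ± 0.03, Klf2 at -0.40 ± 0.05, Klf4 at -0.36 ± 0.03, Nanog at -0.23 ± 0.03, Esrrb at -0.20 ± 0.03, Tbx3 at -0.17 ± 0.04 and Tfcp2l1 at -0.12 ± 0.03. Core genes had 0 higher and 14 lower of 18 (0 and 15 adjusted over the list alone), with Sox2 at -0.36 ± 0.05, while Pou5f1 (-0.01 ± 0.02) did not pass. The p53 target list had 0 higher and 12 lower of 19 (0 and 15 adjusted over the list alone) and cell cycle genes 0 higher and 19 lower of 29 (0 and 23 adjusted over the list alone). The m6A machinery list had 0 higher and 8 lower of 15 (0 and 10 adjusted over the list alone). Formative and primed genes had 0 higher and 8 lower of 14 (0 and 9 adjusted over the list alone). Histone genes had 0 higher and 12 lower of 21 (0 and 12 adjusted over the list alone) and zinc-finger genes 1 higher and 101 lower of 307 (1 and 115 adjusted over the list alone). The steepest falls seen in all 4 conditions were Pim3 (-0.53 ± 0.05), the histone genes H2ac15 (-0.48 ± 0.07) and H2bc8 (-0.46 ± 0.06), Fam43a (-0.48 ± 0.10), Arc (-0.47 ± 0.09), Zfp296 (-0.46 ± 0.04), Zmynd19 (-0.44 ± 0.04) and Med17 (-0.44 ± 0.04). Rises, relative to the scaling, were led by N4bp2l1 (0.27 ± 0.08), Cacng2 (0.27 ± 0.07), Tex14 (0.25 ± 0.04), Ugt2b1 (0.25 ± 0.07), Osbpl3 (0.24 ± 0.06), Calhm6 (0.23 ± 0.08), B3gat2 (0.22 ± 0.07) and S100a4 (0.20 ± 0.06).

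By limma, 30 genes had a positive and 2723 a negative mean slope, and 20 and 2099 of them kept that sign from 0 to 8 h in all 4 conditions. Equal column totals gave 175 positive and 1165 negative slopes, and median-ratio scaling 230 and 830. The total of 2753 was 1636 without the variance trend, 956 for a step after 0 h and 633 without both EB libraries of 8 h. It was 919 and 988 without the KO EB library of 0 or 8 h, 1446 and 1487 without the KO ESC library of 0 or 8 h, 1437 and 1607 without the WT EB library of 0 or 8 h, and 1564 without the WT ESC library of 0 h.

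**Figure D3:**
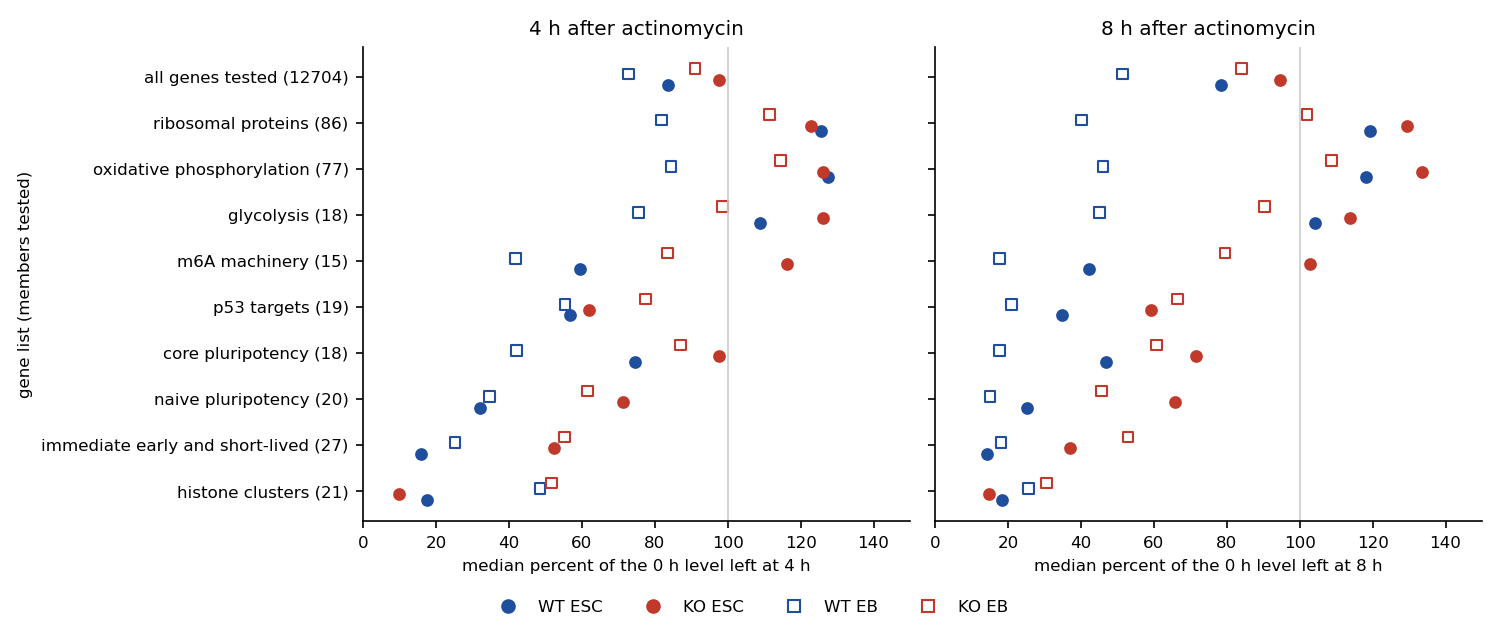
Median percent of the 0 h level left at 4 h (first panel) and 8 h (second panel) after actinomycin, as deposited, for all genes tested and 9 gene lists; the number of genes is in parentheses, blue is WT, red is KO, filled circles are ESCs and open squares EBs, 1 library per time. The naive list kept 31.9% at 4 h in WT ESCs and 71.4% in KO ESCs, and the histone list 17.6% and 9.8%.

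Whether transcripts lasted longer without Mettl3 was asked first in ESCs. At 4 h, 3.86% of the 0 h level of Klf2 was left in WT ESCs and 63.2% in KO ESCs. The share left was 9.21% against 48.9% for Klf4, 11.3% against 63.7% for Zfp42, 21.6% against 104% for Tbx3 and 8.78% against 38.2% for Sox2. It was 81.1% against 176% for Esrrb, 55.2% against 58.6% for Nanog, 109% against 79.8% for Tfcp2l1 and 127% against 137% for Pou5f1. At 8 h it was 2.25% against 41.2% for Klf2, 2.47% against 26.3% for Klf4, 4.71% against 45.7% for Zfp42 and 16.4% against 76.3% for Tbx3. The gap was smaller at 8 h than at 4 h for Sox2 (13.3% against 21.6%). It was 30.1% against 141% for Esrrb, 37.2% against 57.8% for Nanog, 70.0% against 41.7% for Tfcp2l1 and 126% against 138% for Pou5f1. The lowest of these shares rest on few reads, so that they can be several times higher by counting error alone. The WT ESC level at 8 h was 1.9 read equivalents for Klf4 (62.8, 95% counting interval 7.13 to 232), 3.8 for Klf2 (125, 32.7 to 326.5) and 12.5 for Zfp42 (408, 214 to 706). The naive list as a whole kept a median of 25.3% at 8 h in WT ESCs and 65.7% in KO ESCs, against 78.4% and 94.5% for all genes tested. Immediate early genes kept 14.3% and 36.9%, and m6A machinery genes 42.3% and 103%, while histone genes kept 18.2% and 14.7%.

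Few of these differences passed as slopes on a straight line. By limma, 5 genes had a higher slope in KO than in WT ESCs and 0 a lower one (1268 genes at an unadjusted p under 0.05): Trp53rkb (0.81 ± 0.13 log2 per hour), Ints5 (0.55 ± 0.09), Mfsd5 (0.48 ± 0.08), Taf5l (0.48 ± 0.08) and Tsc22d1 (0.47 ± 0.06). None of the 9 pluripotency genes passed: Klf2 had a slope difference of 0.51 ± 0.14 (adjusted p 0.178), Klf4 of 0.41 ± 0.10 (adjusted p 0.133) and Zfp42 of 0.41 ± 0.09 (adjusted p 0.103). Others were 0.28 for Esrrb, 0.27 for Tbx3, 0.08 for Nanog, 0.08 for Sox2, 0.02 for Pou5f1 and -0.09 for Tfcp2l1. Over all genes tested 0 of 20 naive genes and 0 of 27 immediate early genes passed by limma, and 6 and 4 were higher when adjusted over the list alone. The median slope difference of the naive list, 0.17 above that of all genes, lay at percentile 100 of matched random lists, and that of the immediate early list, 0.20 above, at 100. The 5 calls became 59 with a filter of 20 ppm and 42 with shared curvature, and 0 or 1 under each rescaling of the libraries. They became 0 to 2 without any 1 library other than WT ESC at 8 h, and 10 without that one.

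In EBs, more genes passed. By limma, 151 genes had a higher slope in KO than in WT EBs and 0 a lower one (2143 genes at an unadjusted p under 0.05). The largest were Ppcs (0.60 ± 0.11 log2 per hour), Itpka (0.58 ± 0.13), Mrm3 (0.57 ± 0.13), Ccdc71 (0.57 ± 0.08), Rad54l2 (0.56 ± 0.11) and Ankrd46 (0.55 ± 0.11). The called genes held Esrrb (0.45 ± 0.08) and Nr0b1 (0.39 ± 0.07) of the naive list, 2 higher and 0 lower of 20 (2 and 0 adjusted over the list alone). They also held Utf1 (0.43 ± 0.08), Pou5f1 (0.22 ± 0.05) and Jarid2 (0.39 ± 0.09) of the core list, 3 higher and 0 lower of 18 (11 and 0 adjusted over the list alone). The m6A machinery list had 3 higher and 0 lower of 15 (7 and 0 adjusted over the list alone), with Ythdf2 at 0.47 ± 0.07 and Wtap at 0.35 ± 0.08. Values for Klf2 (0.37), Zfp42 (0.26), Nanog (0.20), Sox2 (0.28), Tfcp2l1 (0.14, which turned to -0.03 under ribosomal protein scaling), Klf4 (0.03, negative under each rescaling) and Tbx3 (-0.004) did not pass. At 8 h, 4.56% of the 0 h level of Esrrb was left in WT EBs and 60.4% in KO EBs, and 11.9% against 59.4% under ribosomal protein scaling. For Nanog it was 8.88% against 29.3%, and 23.2% against 28.8% under that scaling. For Klf2 it was 3.92% against 32.7% (10.3% against 32.1% under that scaling) and for Zfp42 4.18% against 19.5% (10.9% against 19.2%). It was 4.56% against 23.2% for Sox2 (11.9% against 22.8%) and 36.7% against 125% for Pou5f1 (95.9% against 123%). For Tfcp2l1, 32.3% against 71.9% turned to 84.5% against 70.6% under that scaling. For Klf4 it was 16.8% against 21.8%, which turned to 36.2% against 27.0% under median-ratio and 44.0% against 21.4% under ribosomal protein scaling. For Tbx3 it was 40.0% against 39.4%, which turned to 86.1% against 48.8% under median-ratio and 104% against 38.7% under ribosomal protein scaling. The WT EB levels at 8 h behind these shares were 3.1 read equivalents for Klf4, 4.8 for Esrrb, 4.9 for Nanog and 9.9 for Tbx3. They were 4.1 for Zfp42, 5.2 for Sox2, 8.6 for Klf2, 15.9 for Tfcp2l1 and 303.1 for Pou5f1.

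These calls in EBs depended on the scaling between libraries, of which WT EBs at 8 h had the lowest total. The median over all genes was 0.08 per hour as deposited and turned to -0.03, -0.01 and -0.08 under equal column totals, median-ratio and ribosomal protein scaling. Relative to it the core list lay at 0.13 and the m6A machinery list at 0.18. Under those scalings limma called 0, 0 and 6 genes, the 6 with a lower slope in KO EBs. The count was 0 without both EB libraries of 8 h, without the variance trend or for a step after 0 h, 4 without a filter, 97 with a pseudocount of 0.2 ppm, 701 with a filter of 20 ppm and 772 with shared curvature. It was 0 without any 1 of the 6 KO libraries or the WT EB library of 8 h, and 26, 32 and 27 without the WT ESC library of 0, 4 or 8 h. Without the WT EB library of 4 h it was 443. Under equal column totals, median-ratio and ribosomal protein scaling, the uncalled slope differences were 0.335, 0.358 and 0.284 for Esrrb and 0.097, 0.122 and 0.045 for Pou5f1. Without the KO EB library of 0 or 8 h or the WT EB library of 8 h they were 0.392, 0.508 and 0.51 for Esrrb and 0.188, 0.254 and 0.113 for Pou5f1, uncalled too. Without the KO EB library of 4 h or any 1 KO ESC library, without the variance trend and with no filter, both kept their size (0.45 and 0.221) and lost their calls. Esrrb (0.39) lost its call without the WT EB library of 0 h as well, and Pou5f1 without any 1 WT ESC library and with a pseudocount of 0.2 ppm (0.222).

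Whether the effect on slopes differed between EBs and ESCs was tested too. By limma, 0 genes passed, with 960 at an unadjusted p under 0.05 and a smallest adjusted p of 0.61. The smallest p-values were those of Pfas (0.61 ± 0.13), Zbed5 (0.68 ± 0.16) and Dcp2, which encodes a decapping enzyme (0.59 ± 0.14), with the higher slope difference in EBs. In the other direction they were those of Zfp131 (-0.79 ± 0.20), Exo5 (-0.80 ± 0.21) and Vipas39 (-0.76 ± 0.21), with the higher one in ESCs. Esrrb had 0.17 ± 0.11, Nanog 0.12 ± 0.10 and Klf4 -0.38 ± 0.14. Shared curvature gave 5 calls, and leaving out the KO EB library of 0 h gave 1.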

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

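The tests chosen only after the result was seen were the counts over other splits of the libraries, the count of endoderm genes under other scalings, the median of the naive list under other scalings and the matching of random lists on the WT ESC slope.

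The difference between KO and WT cells itself differed between EBs and ESCs for 363 genes in limma's test of the level interaction (adjusted p under 0.05). As the KO minus WT difference in EBs less that in ESCs, the log2 values were 2.04 for Nanog, 1.47 for Esrrb, 1.36 for Pou5f1, 6.19 for Tex13b, 6.05 for Stra8, 4.81 for Kiss1, 4.75 for Usp26, 4.28 for Col9a2 and 4.18 for Cdx1. The largest in the other direction were S100g at -7.83, Fxyd3 at -7.21, Pga5 at -7.18, Car4 at -6.98, Pth1r at -6.72 and Apom at -6.44. The count fell to 42 without both EB libraries of 8 h, where the EB levels are those of 4 h alone. Of 100 splits of the libraries, 3 gave as many genes, the real one included. The highest other split gave 1362 genes, several times the real count, and the cause of that was not tested. The other splits mix times within a group and put genotype differences into the scatter, so that this share does not settle whether chance gives such a count.

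The first pattern weighed is the endoderm genes, of which 20 of 27 in the lists of definitive, visceral and parietal endoderm were lower in KO than in WT EBs. Under each of the 3 other scalings 20 of these 20 were still called lower. Those scalings moved the median over all genes from 0.09 to -0.14, -0.09 and -0.22, towards lower in KO EBs, so that this count could hardly fall. The list medians of -2.41 and -3.23 lie far beyond those shifts, which argues against the scaling as the whole cause. After background was subtracted 20 were still called lower, which argues against background reads as the whole cause. Slower differentiation without Mettl3 may explain the 20 calls, but so may a difference between cultures in the size, age or make-up of the EBs. Neither was tested, since no group had a replicate culture.

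The second pattern is that every one of the 151 slope calls in EBs was positive. Of the genes at an unadjusted p under 0.05, 98.0% had the higher slope in KO EBs as deposited, and under median-ratio scaling 593 of 838 did (70.8%). The median over the called genes went from 0.35 log2 per hour (median SE 0.071) to 0.229 under equal column totals, 0.254 under median-ratio and 0.177 under ribosomal protein scaling. The smallest adjusted p by limma over all genes tested, called or not, was 0.0539, 0.176 and 0.00421. The last belongs to a gene with a lower slope in KO EBs, as did all 6 calls under ribosomal protein scaling. The calls of a higher slope ended as the differences of these genes shrank with the scaling. Oxidative phosphorylation genes had not fallen by 8 h in ESCs, with a median of 118.3% left in WT and 133.5% in KO. In EBs 46.0% was left in WT and 108.7% in KO, as deposited. Their median slope difference in EBs was 0.147 per hour, and 0.023, 0.048 and -0.028 under the scalings in the same order. That gap may be scaling in part, but it rests largely on the WT EB library of 8 h. For the called genes, the scaling and longer-lived transcripts in KO EBs cannot be told apart here. How the levels were scaled is not given in the sources used, and no outside standard was at hand to fix them between libraries.

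The third pattern is the naive list, whose median slope difference in ESCs was 0.211 per hour, and 0.185, 0.189 and 0.174 under equal column totals, ribosomal protein and median-ratio scaling (bootstrap SE over members 0.055, 0.054 and 0.056), which argues against the scaling as the whole cause. A weaker block of transcription in KO ESCs would raise the slopes of all short-lived transcripts: the list lay at percentile 99.89 of lists matched on the slope in WT EBs (median 0.083), which is past the upper bound that had been set, before the result was seen, for excluding this. That bound was inadequate, because the lists so matched fell by 0.126 per hour in WT ESCs and the naive list by 0.266. Matched on the WT ESC slope instead (-0.22 per hour, median 0.152) the list lay at percentile 93.68, although that matching itself favours the random lists, since the WT ESC slope is part of the difference. A weaker block and a longer life of naive transcripts without Mettl3 cannot be told apart. The immediate early list, short-lived too, had a median difference of 0.243 (percentile 100), above that of the naive list, and 0.199 under median-ratio scaling. Histone genes had a median difference of 0.013 (percentile 23.55), which was -0.009 and -0.016 under equal column totals and median-ratio scaling. The histone list stood at 17.6% in WT and 9.8% in KO ESCs at 4 h, and at 18.2% and 14.7% at 8 h. It fell no further after 4 h, so that a straight line describes it poorly and its slope difference decides little.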

How the results depend on the processing

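The tests chosen only after the result was seen were a step after 0 h, the fit without both EB libraries of 8 h, background subtraction and list medians relative to all genes. Of the counts under all alternatives, 111 stayed within 1.5 times the value reported, 90 were smaller and 10 larger. Of the values of the 9 pluripotency genes, 734 kept their direction and side of the threshold, 64 fell short of it, 21 newly passed and 27 changed sign.

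Under equal column totals 2012 genes differed between EBs and ESCs in WT and 237 in KO cells, 1340 had a mean slope, and 1 and 0 a slope difference in ESCs and EBs. Median-ratio scaling gave 2024, 166, 1060, 0 and 0. Ribosomal protein scaling gave 1930 and 390 for the cell types, and 1 and 6 for slope differences. Without the variance trend, KO differed from WT for 1047 genes in ESCs and 353 in EBs, cell types in KO for 111, the interaction for 63, the mean slope for 1636, and both slope differences for 0. Additive time terms gave 1043 and 475 for KO against WT in ESCs and EBs and 1809 for the cell types in KO. No filter on low values gave 204 for the interaction and 0 and 4 slope differences in ESCs and EBs, where more genes were tested, and a filter of 20 ppm, with fewer genes tested, 59 and 701. A pseudocount of 0.2 ppm gave 0 and 97, and one of 5 gave 1 in ESCs. Shared curvature gave 613 for the interaction, 42 and 772 for the slope differences and 5 for the slope interaction. A step after 0 h gave 956 for the mean slope and 0 and 0 slope differences. Without both EB libraries of 8 h, which leaves fewer samples, EB levels are those of 4 h alone and EB slopes run from 0 to 4 h. The counts were then 126 for KO against WT in EBs, 1662 and 278 for cell types in WT and KO, 42 for the interaction, 633 for the mean slope and 0 and 0 for slope differences. Background subtraction gave 1803 for KO against WT in EBs. Apart from the changes in samples or genes tested, the cause was not tested.

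With each library left out in turn, the lone libraries being taken to vary like the others, counts ran from 717 to 1794 for KO against WT in ESCs, 251 to 1248 in EBs, 2094 to 4258 for cell types in WT, 172 to 3387 in KO, 96 to 406 for the interaction, 919 to 3040 for the mean slope, 0 to 10 and 0 to 443 for the slope differences in ESCs and EBs, and 0 to 1 for the slope interaction. Without a library of 0 or 8 h the level of its condition is that of 4 h alone, so that the level compared changes as well.

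The values that changed sign belong to genes past no threshold. Tbx3 in KO against WT ESCs (0.00) became 0.005 with a pseudocount of 0.2 ppm, 0.172 under ribosomal protein scaling and 0.01 with background subtracted. It ran from -0.298 to 0.596 with each library left out. The Klf4 slope difference in EBs (0.031) became -0.009 with a pseudocount of 5 ppm, and -0.081, -0.058 and -0.131 under equal column totals, median-ratio and ribosomal protein scaling. It ran from -0.039 to 0.101 with each library left out. The Pou5f1 slope difference in ESCs (0.017) became -0.01, -0.023 and -0.004 under these scalings, and ran from -0.038 to 0.071. The Tfcp2l1 slope difference in EBs (0.141) became -0.032 under ribosomal protein scaling and ran from -0.046 to 0.329, and in ESCs (-0.093) it ran from -0.187 to 0.001. The Tbx3 slope difference in EBs (-0.004) became 0.304 for a step after 0 h and 0.161 without both EB libraries of 8 h, and ran from -0.302 to 0.293. In ESCs that of Nanog (0.079) ran from -0.015 to 0.173 and that of Sox2 (0.084) from -0.421 to 0.59.

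List medians were recomputed under 2 scalings for the 54 medians, from 6 comparisons, that lay outside the central 95% of random lists. Of these values 22 changed sign, 67 moved and 19 did not, while relative to all genes 4 moved and 104 did not. Over all lists and comparisons, 97 of 225 medians changed sign under at least 1 of the 3 scalings. Under median-ratio and ribosomal protein scaling, the change from ESC to EB in KO cells became 0.55 and 0.37 for formative (-0.06 as deposited), 0.57 and 0.38 for immediate early (-0.04), 0.32 and 0.12 for p53 target (-0.35), 0.43 and 0.24 for glycolysis (-0.21) and 0.33 and 0.14 for ribosomal protein genes (-0.34). In WT cells it became 0.21 and 0.50 for p53 targets (-0.43) and, under ribosomal protein scaling, 0.12 for ribosomal proteins (-0.87). KO against WT in EBs became -0.13 and -0.27 for cell cycle genes (0.05), -0.12 and -0.26 for the proteasome (0.07) and, under ribosomal protein scaling, -0.10 for zinc-finger genes (0.19). Slope differences in EBs became -0.058 and -0.132 for parietal endoderm (0.044) and -0.026 and -0.097 for zinc-finger genes (0.06). Depth limits low genes most, with 208874 read equivalents in WT EBs at 8 h.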

Other observations

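The tests chosen only after the result was seen were the counts over other splits of the libraries, while the test of the GGACT motif was written before. Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05, the real split included. For KO against WT, 1 of 10 splits gave as many genes in ESCs (1797 against 128 in the highest other) and 1 of 10 in EBs (1171 against 172). For cell types, 1 of 10 did in WT (4145 against 1060) and 1 of 10 in KO cells (3066 against 1). For slope differences, 2 of 10 did in ESCs (5 against 420) and 2 of 10 in EBs (151 against 342). The cause of the 420 genes, many times the real count, was not tested. Of 100 splits for the mean slope, 1 gave as many genes (2753 against 2381 in the highest other), so that a chance order of the times within the conditions is excluded at a share under 0.05. For the slope interaction limma called 0 genes (960 at an unadjusted p under 0.05), a count that any split must reach. That all 100 of 100 did, the highest other giving 460, therefore says nothing about chance, which is not excluded.

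A hypothesis of loss of methylation at GGACT, a common sequence around m6A, in 3′ untranslated regions predicts higher slopes in KO cells for transcripts that carry it. The test ran over all genes for which such a region was found in a transcript matched by RefSeq ID, not over the members of a list. These were 11493, or 90.5% of those tested, and 7000 of them held the motif. Among all pentamers ranked by partial rank correlation with the slope difference, GGACT came at rank 3 in ESCs (0.037) and rank 10 in EBs (0.025). Rank 1 was TGGAG in ESCs (0.043) and GGTTG in EBs (0.031). The most negative values were -0.034 for TACAA in ESCs and -0.035 for CACCC in EBs, so that GGACT lay within the range of other pentamers. Correlations of this size are across genes, which are not independent replicates, and may reflect m6A or other sequence features that go with it. Klf2, whose slope difference in ESCs was 0.51 per hour, held 0 GGACT there, and Tfcp2l1, at -0.09, held 13. Klf4 (0.41), Zfp42 (0.41) and Esrrb (0.28) held 1 each, Tbx3 (0.27) 2 and Sox2 (0.08) 3. Nanog and Pou5f1 were not searched, since no transcript matched to their RefSeq ID with such a region of at least 50 bases was found. Whether the match or the region was lacking was not looked into.

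Of the 1421 genes of silent families only 23 passed the filter on low levels, so that calls among them do not measure background at lower levels. The list had 0 higher and 0 lower calls among these 23 by limma in KO against WT EBs and also in KO against WT ESCs. Between EBs and ESCs it had 2 higher and 4 lower calls in WT cells and 1 higher and 0 lower in KO cells. Of 28 Hox genes, 0 were tested. After actinomycin, the histone list fell to 17.6% of the 0 h level at 4 h in WT ESCs and 9.8% in KO ESCs.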
